A study of Mus musculus with 6 samples.

How the data were processed

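RNA was measured by sequencing in 6 libraries of sorted aTreg, 3 WT and 3 BMPR1a-deficient. Per the labels' protocols, total RNA was extracted with a Qiagen kit and libraries were made with standard Illumina protocols. The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, one column per library. TopHat2, Cufflinks and Cuffdiff are named per the submitters' processing notes, with the genome build GRCm38.p4. Their versions, settings, strand handling and annotation are not given in the sources used here, nor is any scaling between libraries. FPKM carry no counts, so no count model was used, and values of very short features are unreliable because few fragments fit inside them.

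The table held 25759 gene identifiers. Symbols, positions, biotypes, transcript lengths and GC content came from the GENCODE annotation of GRCm38, which matched 24876 identifiers (96.6%) and left 883 without a symbol. Columns were assigned to samples by name, and 0 columns were left unmapped. No columns were identical, and the correlations between libraries lay between 0.879 and 0.924.

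Depth was estimated because the table gives no counts. It used 4534 genes of a set range of lengths whose longest transcript is as long as all their annotated exons together. In these, FPKM times length has a densest low value that stands for about 1 fragment, and this gave 30400000 to 38800000 fragments per library. That value was searched only within a set range, which bounds the depths it could return. The estimate ignores the effective length that Cufflinks uses and is approximate.

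Genes with a mean FPKM of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the factor, eBayes with a trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, BMPR1a-deficient minus WT, and understate the change of low genes. In data simulated on the 13413 tested genes with 100 genes changed at each size, this fit recovered 59% of changes of log2 1 and 87% of log2 2. Of its 162 calls, 9.88% were not changed. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 2, so recovery of lower genes such as Bmpr1a was not measured. Noise was drawn independently for each gene and library, without an outlying library.

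Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over the 39 lists with at least 3 members tested, and again with an estimated correlation. The 41 lists cover T cell programmes, BMP and TGF-beta signalling, metabolism, stress, other cell types and RNA quality, and 841 of their 865 entries were found. The erythroid and platelet list and the stromal and endothelial list had too few tested members. With an estimated correlation camera called 0 lists, and 0 lists had an unadjusted p under 0.05.

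The tests, the lists, the main settings and 17 alternatives were fixed before the data were examined, and 3 more alternatives were added afterwards. The named genes are Bmpr1a, the 10 higher and 10 lower called genes with the largest fold change whose groups do not overlap, leaving out predicted, clone-named and joined symbols, up to 4 called members of each list by smallest adjusted p, or up to 2 as values where none was called, and a fixed set of regulatory, effector and BMP-related genes. Genes were left out for length, and some single-gene values are not reported here. Lyz2 was taken from the marker lists after its values were seen. The alternatives varied the pseudocount, the filter, the scaling, the eBayes settings, sample weights, a replicate block, each library left out, the biotypes tested, a GC correction (lowess span 0.3) and genes above 0 in every library.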

Results

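The series measured gene expression in mouse adaptive regulatory T cells (aTreg), CD4 T cells that take on the regulatory T cell transcription factor Foxp3 when they are activated with TGF-beta. Total lymph node and spleen cells of mice aged 8 to 12 weeks were activated for 3 days with the T cell mitogen concanavalin A at 2 µg/ml, TGF-beta at 3 ng/ml and IL-2 at 10 ng/ml, and CD4+ cells carrying the Foxp3-GFP reporter were then sorted. There were 3 wild type (WT) libraries and 3 from BMPR1a-deficient cells, in which a Cre recombinase driven by Cd4 removes BMPR1a, a type I receptor for bone morphogenetic proteins (BMPs). The comparison asks how aTreg differ when this receptor is missing. As described, the sort did not separate cells that gained Foxp3 in culture from any that carried it before. The table gives FPKM values without counts. The size of the smallest steps in those values pointed to depths of about 30400000, 31400000 and 38800000 fragments in the WT libraries. In the BMPR1a-deficient libraries it pointed to about 36000000, 32300000 and 37200000. The labels do not say whether the libraries came from separate animals or cultures, so each p-value measures only the spread between these samples, which may be technical.

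Bmpr1a itself (ENSMUSG00000021796, chromosome 14, 34410734 to 34503341 in GRCm38) was low in both groups and lower in each BMPR1a-deficient library than in any WT library. Its FPKM was 1.39, 2.34 and 1.31 in WT and 0.439, 0.720 and 0.691 in BMPR1a-deficient aTreg, so the deficient mean was 36.7% of the WT mean. The log2 fold change was -0.71 (SE 0.195), and it did not pass the threshold over all genes (limma, adjusted p = 0.184). It passed when adjusted over the list of BMP receptors and SMADs alone (limma adjusted p = 0.0397). An exact permutation test of the 6 values gave a two-sided p of 0.1, the smallest that 3 against 3 samples allow. A gene-level value includes exons that the recombinase does not remove, so it need not fall to 0.

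Of 13413 genes tested, 100 were higher and 43 were lower in BMPR1a-deficient aTreg at an adjusted p under 0.05 in limma. Among the higher genes was Ctse, which encodes the aspartic protease cathepsin E, from 8.00 ± 0.884 to 122 ± 45.2 FPKM (SD, n = 3 per group). Wls, the carrier that brings Wnt proteins to the cell surface, rose from 3.99 ± 0.109 to 30.9 ± 4.36 FPKM. Among the lower genes were Ifi213, from 40.6 ± 13.1 to 1.94 ± 1.17 FPKM, and Tent5a, which encodes a poly(A) polymerase, from 36.0 ± 2.15 to 6.90 ± 2.87 FPKM. The count changed when a library was left out: it was 37 higher and 18 lower without WT replicate 1, 13 and 8 without WT replicate 2, and 10 and 4 without WT replicate 3. It was 134 and 76 without BMPR1a-deficient replicate 1, 34 and 18 without replicate 2 and 15 and 5 without replicate 3 of that group. Each such fit has fewer libraries and so less power, so a lost call need not mean that it rested on the library left out. Of the 143 called genes, 25 were called in 0 of these 6 fits and 80 in only 1. Of the called genes 69.9% were higher, against 55.7% with quantile normalization.

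**Figure D1:**
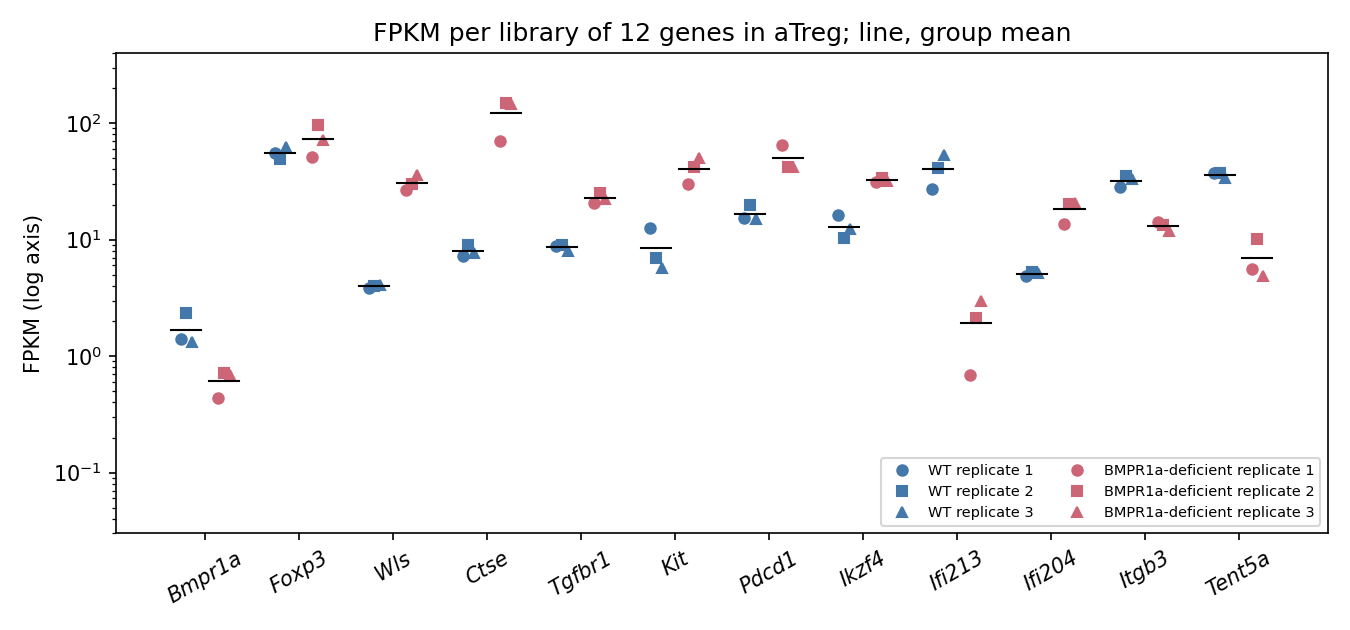
FPKM (log axis) of 12 genes in each library, with symbols for the replicates, colours for the groups and a line at each group mean. Wls lies between 3.87 and 4.09 in WT and between 26.9 and 35.5 in BMPR1a-deficient aTreg, while the Foxp3 values of the groups overlap.

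Among the higher genes named by the rule, the log2 fold change of Ctse was 3.69 (SE 0.309, limma adjusted p = 0.0129) and that of Wls 2.67 (SE 0.120, adjusted p = 0.00115). Ccl1, a chemokine that binds the receptor CCR8, rose by a log2 fold change of 3.17, and Xkr6 and Pianp had log2 fold changes of 2.91 and 2.57. The neighbouring apolipoprotein L genes Apol9b and Apol9a on chromosome 15 rose by 3.13 and 2.77. Apol9a and Apol9b resemble each other closely, so the division of reads between them is uncertain. Wls passed the threshold in all 6 fits that left out a library, Xkr6 in 5 and Ctse in 2. Ccl1, Apol9a and Pianp passed in 1 each and Apol9b in 0. Apol9b was also lost with upper-quartile scaling (limma adjusted p = 0.0556) and quantile normalization (adjusted p = 0.0557). The identifier ENSMUSG00000028269, which has no symbol in the annotation used, rose from 0.598 ± 0.293 to 28.6 ± 6.11 FPKM (SD, n = 3). The small nucleolar RNA Snord16a was listed at 0 in each WT library and at 578, 836 and 849 FPKM in the BMPR1a-deficient ones, and Mir1949 at 0 and at 4.57, 4.47 and 3.53.

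On the lower side, 4 of the 10 genes named by the rule, which leaves out predicted and clone-named genes, belong to the Ifi200 family, interferon-inducible genes side by side on chromosome 1. Ifi213 (173566283 to 173599274) fell by 3.86 on the log2 scale (SE 0.384, limma adjusted p = 0.0172). The log2 fold changes of Ifi206, Ifi208 and Ifi205 were -3.09, -2.79 and -1.63. Ifi204 in the same cluster rose from 4.87, 5.23 and 5.20 FPKM in WT to 13.6, 20.2 and 20.8, a log2 fold change of 1.63 (SE 0.172, adjusted p = 0.0191). These genes are close copies of each other, so how reads were divided between them is uncertain. The membrane carboxypeptidase gene Cpm had a log2 fold change of -2.49 and Tent5a one of -2.28. Sh3bp5, which encodes a protein that binds Bruton's tyrosine kinase, fell by 1.65 on the log2 scale. Of the 6 fits that left out a library, Cpm passed the threshold in 4, Sh3bp5 in 3 and Ifi213 and Ifi208 in 2 each. Ifi206, Ifi205, Ifi204 and Tent5a passed in only 1 each. Ighj4, an immunoglobulin heavy chain joining segment, was listed at 42484, 34991 and 53947 FPKM in WT and at 0 in each BMPR1a-deficient library. The mitochondrial threonine tRNA gene mt-Tt was listed at 2031, 2533 and 1641 FPKM in WT and at 0 in each BMPR1a-deficient library. FPKM is unreliable for features as short as these, and an exact 0 can be a failed estimate. Of the 143 called genes, 8 were at 0 in every library of one group, among them a gene annotated as protein-coding. Because these zeros follow the group, a difference in processing between the groups cannot be told apart from a change in the cells.

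**Figure D2:**
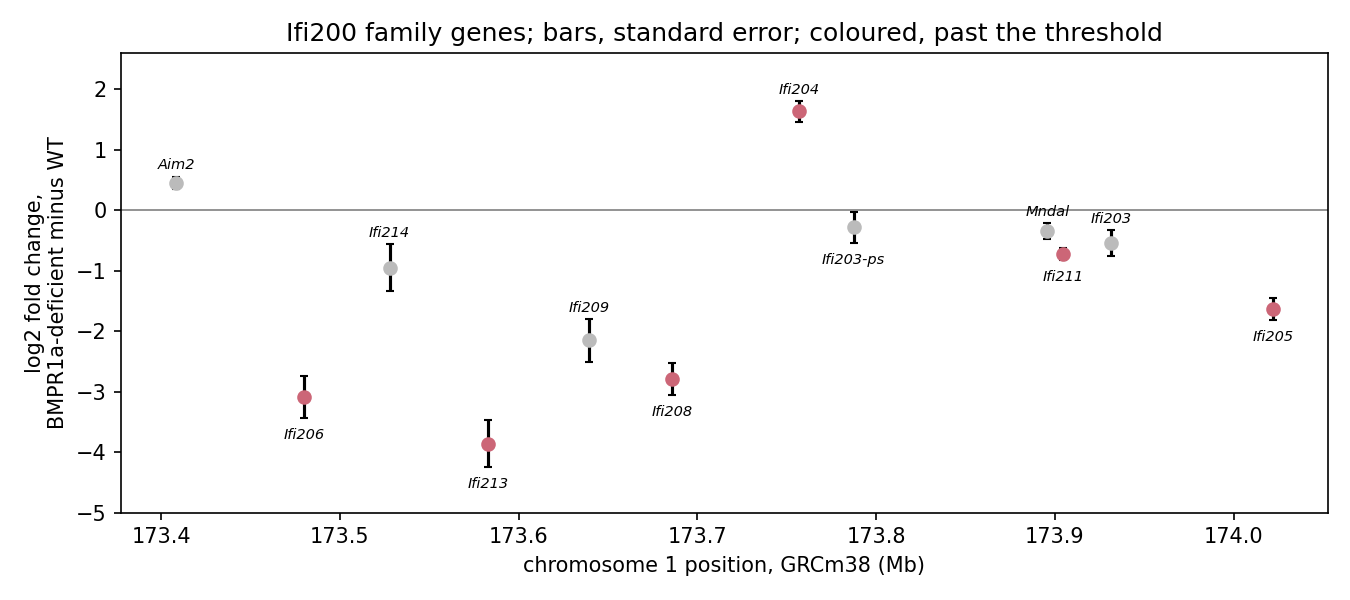
Log2 fold change (BMPR1a-deficient minus WT, bars showing the standard error) of the 12 tested Ifi200 family genes by position on chromosome 1 in GRCm38 (Mb), coloured where past the threshold. Ifi213, Ifi206, Ifi208, Ifi205 and Ifi211 lie below 0 and Ifi204 lies above it at 1.63.

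The regulatory T cell signature was higher as a list with the preset correlation only, with a median log2 fold change of 0.60 (limma camera, adjusted p = 7.12e-05, and adjusted p = 0.785 with an estimated correlation). Of the 29 members tested, 4 were higher and 0 lower over all genes tested, and 13 were higher and 1 lower when adjusted over the list alone. Ikzf4, which encodes the transcription factor Eos, rose from 13.0 ± 2.96 to 32.4 ± 1.15 FPKM (SD, n = 3, log2 fold change 1.28). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose from 133 ± 8.06 to 243 ± 19.8 (0.87). Dusp4 rose from 42.6 ± 5.85 to 88.5 ± 5.24 (1.05) and Swap70 from 14.4 ± 0.698 to 25.9 ± 1.78 (0.81). Dusp4 passed the threshold in 0 of the 6 fits that left out a library and the other three in 1 each. Foxp3 itself was at 55.9 ± 6.43 FPKM in WT and 73.4 ± 22.8 in BMPR1a-deficient aTreg (SD, n = 3, limma adjusted p = 0.523). Il2ra was at 56.6 ± 16.01 and 83.0 ± 20.3 (limma adjusted p = 0.390) and Ctla4 at 254 ± 19.4 and 170 ± 57.9 (adjusted p = 0.361). Ikzf2, which encodes Helios, was at 25.5 ± 6.40 and 47.5 ± 4.49 (limma adjusted p = 0.104). None of these 4 passed the threshold. Whether the groups differed in the share of cells that carried Foxp3 before culture was not tested.

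Of the 19 tested members of the TGF-beta pathway list, 1 passed the threshold over all genes. This was Tgfbr1, the type I TGF-beta receptor, which rose from 8.60 ± 0.571 to 22.7 ± 2.15 FPKM (SD, n = 3, log2 fold change 1.30, limma adjusted p = 0.0116). Tgfbr1 passed in 3 of the 6 fits that left out a library. Of the list, 7 were higher and 1 lower adjusted over the list alone. Tgfbr2, the type II receptor, was at 61.6 ± 4.40 and 63.3 ± 9.01 FPKM. The list's median log2 fold change was 0.25 (camera, adjusted p = 0.00679, and adjusted p = 0.785 with an estimated correlation), and its call was lost without WT replicate 2 (adjusted p = 0.0951). In the list of BMP receptors and SMADs, 1 of 15 tested members fell over all genes, and 1 was higher (Bmpr2) and 3 lower (Acvrl1, Bmpr1a and Smad3) adjusted over the list alone. Acvrl1, a type I receptor of the same family, went from 7.60 ± 1.39 to 3.35 ± 0.198 FPKM (log2 fold change -0.97, limma adjusted p = 0.0477). That call was lost in all 6 fits that left out a library, with upper-quartile scaling (limma adjusted p = 0.0586), with quantile normalization (adjusted p = 0.0713) and with a replicate block (adjusted p = 0.149). Bmpr2, the type II partner of BMPR1a, was at 1.90 ± 0.319 and 3.61 ± 0.268 FPKM (adjusted p = 0.0871) and Acvr1 at 0.916 ± 0.121 and 1.52 ± 0.543 (adjusted p = 0.434). That list did not pass the threshold (camera, adjusted p = 0.432), nor did the 4 tested BMP-responsive genes (adjusted p = 0.432). Among these genes Id2 was at 22.1 ± 3.55 and 14.1 ± 7.38 FPKM and Id3 at 39.4 ± 7.61 and 32.3 ± 5.63. Smad7 lay the other way, at 24.7 ± 3.84 and 31.8 ± 3.73 FPKM (limma adjusted p = 0.337). Id1 was below the filter.

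Of 25 tested p53 target genes 1 was higher, both over all genes and adjusted over the list alone: Pmaip1, which encodes the apoptosis inducer Noxa, rose from 3.13 ± 0.720 to 10.6 ± 0.717 FPKM (SD, n = 3, log2 fold change 1.501, limma adjusted p = 0.0182). Pmaip1 passed the threshold in only 1 of the 6 fits that left out a library. The list's median was 0.25 (camera, adjusted p = 0.0133, and adjusted p = 0.829 with an estimated correlation), and its call was lost without BMPR1a-deficient replicate 3 (adjusted p = 0.141). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 9.52 ± 8.06 and 17.0 ± 6.998 FPKM (limma adjusted p = 0.450), and Kdm6b, which encodes a demethylase of histone H3 lysine 27, at 8.78 ± 1.42 and 15.2 ± 3.47 (adjusted p = 0.165). The 41 tested cell cycle and DNA replication genes had 0 members past the threshold, over all genes or adjusted over the list alone, and 39 positive fold changes with a median of 0.30 (camera, adjusted p = 0.000322, and adjusted p = 0.840 with an estimated correlation). That call was lost without WT replicate 3 (adjusted p = 0.0698) and without BMPR1a-deficient replicate 1 (adjusted p = 0.0776).

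Single genes of activated or cytotoxic T cells passed the threshold, but the list of immediate early and T cell activation genes did not (camera, adjusted p = 0.806), nor did the list of cytokines and cytolytic molecules (adjusted p = 0.513). Klrd1, a receptor gene of NK and cytotoxic cells, was at 84.8 ± 26.2 FPKM in WT and 23.4 ± 12.5 in BMPR1a-deficient aTreg (SD, n = 3, limma adjusted p = 0.115). Pdcd1, which encodes the inhibitory receptor PD-1, rose from 16.7 ± 2.83 to 49.8 ± 13.5 FPKM (SD, n = 3, log2 fold change 1.496). Nkg7, a gene of cytotoxic granules, rose from 67.0 ± 13.0 to 186 ± 12.3 (1.48). The chemokine gene Xcl1 rose from 51.2 ± 22.4 to 222 ± 39.2 (2.16) and the chemokine receptor gene Cx3cr1 from 0.760 ± 0.465 to 6.32 ± 1.02 (2.08). Kit, the receptor for stem cell factor, rose from 8.43 ± 3.74 to 40.5 ± 10.3 (2.18) and Tnfrsf1b, which encodes TNF receptor 2, from 41.9 ± 10.4 to 104 ± 7.02 (1.31). Stat5a, a signal transducer of IL-2, rose from 49.1 ± 1.42 to 82.2 ± 6.34 FPKM (0.73), and the activation-induced Nr4a3 and Dusp5 had log2 fold changes of 0.79 and 0.82. The call of Kit was lost in all 6 fits that left out a library, with upper-quartile scaling (limma adjusted p = 0.0546) and with quantile normalization (adjusted p = 0.0538). Upper-quartile scaling also ended the calls of Xcl1, Tnfrsf1b and Dusp5 (limma adjusted p = 0.0546, 0.0551 and 0.0514), and the GC correction that of Stat5a (adjusted p = 0.0680). The inhibitory receptor gene Btla fell from 25.9 ± 1.85 to 14.95 ± 1.07 FPKM (-0.76) and the integrin gene Itgb3 from 32.2 ± 3.56 to 13.1 ± 1.18 (-1.23). Of the 6 fits that left out a library, Nkg7, Cx3cr1 and Itgb3 passed the threshold in 2 each. Pdcd1, Xcl1, Tnfrsf1b, Stat5a, Nr4a3, Dusp5 and Btla passed in only 1 each. The lists for Th1, Th2, Th17 and Tfh cells did not pass the threshold (camera, adjusted p = 0.145, 0.518, 0.934 and 0.413). Tbx21 was at 9.28 ± 1.91 and 12.5 ± 1.42 FPKM and Ifng at 2.14 ± 1.07 and 5.01 ± 0.764. Gata3 was at 23.7 ± 3.91 and 33.6 ± 3.02, Il17a at 1.497 ± 0.0372 and 1.12 ± 1.28 and Cd4 at 343 ± 14.9 and 378 ± 49.4, with no gene of these past the threshold in limma.

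The list of naive and memory T cell genes was lower with the preset correlation only, with a median of -0.65 (camera, adjusted p = 7.12e-05, and adjusted p = 0.785 with an estimated correlation). Of 21 tested members 0 were higher and 1 was lower over all genes, and 4 were lower adjusted over the list alone. Dapl1 fell from 186 ± 25.5 to 78.0 ± 9.51 FPKM (SD, n = 3, log2 fold change -1.24, limma adjusted p = 0.0308). Its call held in only 1 of the 6 fits that left out a library. The list's mean relative to WT was -0.80 in BMPR1a-deficient replicate 1 and -0.30 and -0.32 in replicates 2 and 3. The 29 tested type I interferon response genes had a median of -0.43 (camera, adjusted p = 0.000105, and adjusted p = 0.829 with an estimated correlation), with a mean of -0.73 in replicate 1 and -0.19 and -0.07 in the others. Its 2 members past the threshold, Ifi204 and Isg20, both went the other way. Isg20, an interferon-induced exonuclease gene, rose from 7.16 ± 0.696 to 15.6 ± 0.830 FPKM and passed the threshold in 2 of the 6 fits that left out a library. Adjusted over the list alone 2 were higher and 1 lower.

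Of the 21 tested glycolysis genes 0 passed over all genes, and 1 was higher and 5 were lower adjusted over the list alone. Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, was at 66.2 ± 20.7 FPKM in WT and 23.3 ± 2.54 in BMPR1a-deficient aTreg (SD, n = 3, limma adjusted p = 0.0725) and Pfkfb3 at 18.4 ± 1.15 and 26.8 ± 0.583 (adjusted p = 0.0647). The list was lower with a median of -0.28 (camera, adjusted p = 0.000456, and adjusted p = 0.785 with an estimated correlation). The 19 cholesterol synthesis genes had 0 past the threshold over all genes and 1 lower adjusted over the list alone. Their median was -0.16 (camera, adjusted p = 0.00133, and adjusted p = 0.829 with an estimated correlation), a call lost without WT replicate 2 (adjusted p = 0.0571). The 22 T cell receptor and costimulation genes had a median of -0.12 with 0 members past the threshold (camera, adjusted p = 0.0268, and adjusted p = 0.785 with an estimated correlation), a call lost without WT replicate 1 (adjusted p = 0.132) and without BMPR1a-deficient replicate 3 (adjusted p = 0.127), with quantile normalization (adjusted p = 0.822) and with a replicate block (adjusted p = 0.0688).

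Lists that track RNA quality also passed the threshold with the preset correlation only, except the nuclear-retained long noncoding RNAs. The 4 tested genes of that list had a median log2 fold change of -0.40 (camera, adjusted p = 0.0726). The 18 tested replication-dependent histone genes had a median log2 fold change of -0.36, with 0 past the threshold over all genes and 3 lower adjusted over the list alone (camera, adjusted p = 2.28e-05, and adjusted p = 0.785 with an estimated correlation). The 15 mitochondrially encoded transcripts had a median of -1.18 (camera, adjusted p = 0.000440, and adjusted p = 0.840 with an estimated correlation), with a mean relative to WT of -3.22 in BMPR1a-deficient replicate 1 and -0.20 and -0.21 in replicates 2 and 3. The 35 ribosomal protein genes had a median of -0.12 (camera, adjusted p = 0.0269, and adjusted p = 0.785 with an estimated correlation), and their direction turned with quantile normalization (shift 0.09, adjusted p = 0.598). That call was also lost with a replicate block (adjusted p = 0.0839) and without WT replicate 1 (adjusted p = 0.129), BMPR1a-deficient replicate 2 (adjusted p = 0.173) or replicate 3 (adjusted p = 0.217).

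**Figure D3:**
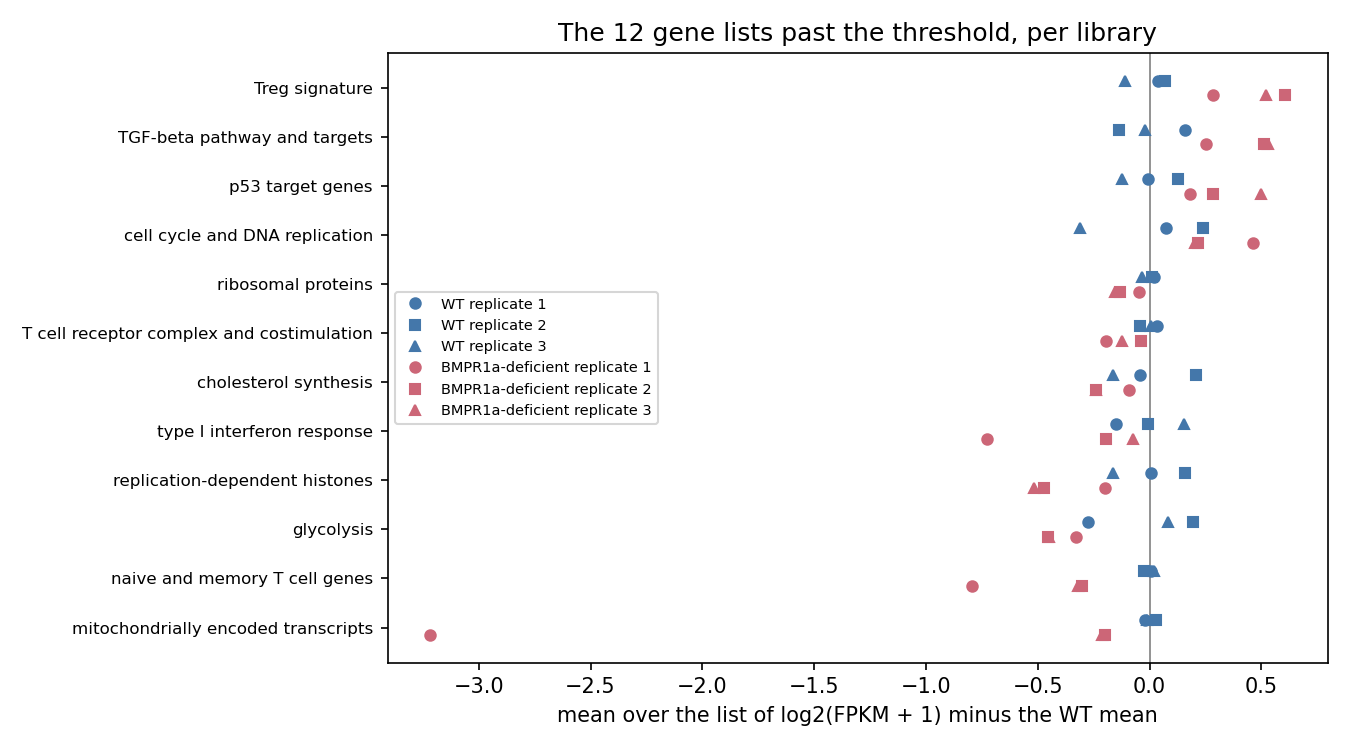
Mean over each of the 12 gene lists past the threshold of log2(FPKM + 1) minus the WT mean, one symbol per library. BMPR1a-deficient replicate 1 lies at -3.22 for the mitochondrially encoded transcripts, against -0.20 and -0.21 in the other BMPR1a-deficient libraries; with quantile normalization the ribosomal protein list changes direction.

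Markers of other cell types were measured because the cells were sorted from a mixed culture. None of the 7 tested marker lists passed the threshold with all libraries and the fixed settings: camera gave adjusted p = 0.316 for B cell, 0.176 for macrophage and monocyte, 0.164 for dendritic cell and MHC class II, 0.432 for neutrophil, 0.774 for NK cell, 0.988 for CD8 T cell and 0.502 for mast cell and basophil markers. Under single alternatives some did pass in camera: B cell (adjusted p = 0.0154) and dendritic cell markers (adjusted p = 0.0360) were higher without WT replicate 3, and neutrophil markers were higher without a filter on low values (adjusted p = 0.00974). Macrophage and monocyte markers were lower without WT replicate 2 (camera, adjusted p = 0.0163) or BMPR1a-deficient replicate 3 (adjusted p = 0.00499), while their median turned from -0.25 to 0.20 without BMPR1a-deficient replicate 1. Levels varied between libraries of a group: the lysozyme gene Lyz2 was at 84.5, 14.5 and 30.9 FPKM in WT and 8.71, 35.6 and 72.8 in BMPR1a-deficient aTreg, and the neutrophil gene S100a8 at 13.99, 0.603 and 3.12 and at 3.99, 24.8 and 67.1. The B cell marker Cd72 rose from 41.1 ± 4.63 to 72.6 ± 0.924 FPKM (SD, n = 3, limma adjusted p = 0.0405). That call was lost in all 6 fits that left out a library, with upper-quartile scaling (limma adjusted p = 0.0611) and with quantile normalization (adjusted p = 0.0599). Kit, a member of the mast cell and basophil list, and Nkg7, a member of the NK cell list, were also called higher, as given above. Median, mean and tested direction differed in sign for 6 lists, none past the threshold: CDK inhibitors, mast cell and basophil markers, Th17 genes, H3K27 methylation regulators, interferon-gamma response and CD8 T cell markers.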

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

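The protein-coding, GC-corrected and above-0 settings were chosen after seeing the data. The genes higher and lower (100 and 43) became 833 and 407 with array weights, 202 and 94 with protein-coding genes only, and 166 and 69 with genes above 0 in every library; the cause was not tested. Genes lower were 27 at a mean FPKM of at least 5, 70 with quantile normalization and 70 with GC-corrected values; the cause was not tested. Leaving out 1 library gave 10 to 134 genes higher and 4 to 76 lower, and 11 of the 143 called genes were called in all 6 omissions, with 0 changing sign. Of these 11 genes, 6 are listed at 0 in every library of one group. With a replicate block limma called 5 genes higher and 5 lower. The same-number correlations of deviations were 0.010, 0.064 and 0.052, and those between different numbers lay between -0.0935 and 0.0412. Such weak values neither show nor exclude a pairing of the samples by number. Lists higher and lower (4 and 8) became 0 and 0 with an estimated correlation (camera, lowest adjusted p = 0.785). Ribosomal proteins turned to a shift of 0.0925 with quantile normalization (cause not tested). Bmpr1a kept its negative sign and stayed short of the threshold over all genes in every setting in which it was tested (limma adjusted p from 0.0614 to 0.344); at a mean FPKM of at least 5 it was not tested. Of the named genes' other values, 224 fell short of the threshold and 44 newly passed it, while 1641 stayed on their side. Depths of about 30400000 to 38800000 fragments may limit genes near 1 FPKM, Bmpr1a among them, but this was not tested.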

Other observations

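The tests of small RNAs and of transcript length were written before their results were seen; all other tests in this part were chosen after the result was seen, and the genes in the next 2 paragraphs were chosen after their values were seen.

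Some called genes lie outside the fixed lists, and they stand for no group that was tested. Axl, a receptor tyrosine kinase that binds Gas6, rose from 6.31 ± 1.05 to 20.3 ± 1.13 FPKM (SD, n = 3, log2 fold change 1.55, limma adjusted p = 0.0121), Ptger4, a prostaglandin E2 receptor gene, from 7.39 ± 1.04 to 18.1 ± 0.992 (1.19, adjusted p = 0.0172), Ramp1, a part of the receptor for calcitonin gene-related peptide, from 2.96 ± 0.754 to 11.2 ± 1.59 (1.64, adjusted p = 0.0191), and Cdh1, which encodes E-cadherin, from 0.561 ± 0.345 to 5.11 ± 0.346 (1.99, adjusted p = 0.0163). The transcription factor gene Sox4 rose from 4.197 ± 0.463 to 20.2 ± 2.95 FPKM (2.02, adjusted p = 0.00615) and the G protein regulator Rgs16 from 6.70 ± 1.40 to 31.7 ± 2.87 (2.10, adjusted p = 0.00948). Cyp11a1, the first enzyme of steroid synthesis, rose from 0.677 ± 0.0925 to 2.43 ± 0.371 FPKM. Of the GTPase genes Gimap3 and Gimap5, neighbours on chromosome 6, both fell, Gimap3 from 502 ± 42.7 to 253 ± 10.0 FPKM (-0.98, adjusted p = 0.0285) and Gimap5 from 99.8 ± 2.62 to 53.9 ± 6.28 (-0.88, adjusted p = 0.0380). Of the 6 fits that left out a library, Sox4 and Rgs16 passed in 4, Axl in 3, Ptger4 and Cdh1 in 2, and Ramp1, Cyp11a1, Gimap3 and Gimap5 in 1 each.

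Genes known from B cells were also called. Cd40 rose from 4.12 ± 1.11 to 10.2 ± 0.651 FPKM (SD, n = 3, limma adjusted p = 0.0496) and Tnfrsf13c, which encodes the BAFF receptor, from 3.56 ± 0.402 to 9.46 ± 0.547 (adjusted p = 0.0142). The immunoglobulin genes Igha and Ighg3 rose from 8.71 ± 1.95 to 20.9 ± 1.85 (limma adjusted p = 0.0410) and from 1.32 ± 0.164 to 3.98 ± 0.306 (adjusted p = 0.0191). They were the 2 called of 6 tested immunoglobulin constant-region genes. Of 69 tested variable-region genes 0 were called, and of 2 joining segments 1 was called lower (Ighj4). Cd40 and Igha passed in 0 of the fits that left out a library, Ighg3 in 1 and Tnfrsf13c in 2. Of 15 tested B cell markers 13 had positive fold changes, and that list passed the threshold only without WT replicate 3. Its median log2 fold change was 0.22 (SD 0.265), and those of these 4 genes were 1.10 to 1.20. The 4 genes were chosen because they were called, so this difference cannot decide whether more B cells were present. A larger share of B cells and a change in the B cells present both stay open.

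BMPR1a-deficient replicate 1 stood apart from the other libraries. Over nuclear protein-coding genes the SD of the log2 difference between 2 libraries of a group was 0.479 and 0.493 in its pairs, against 0.234 to 0.309 in the 4 other pairs. Relative to the mean of its group mates, genes in the lowest 20% of GC content deviated by -0.33 and those in the highest 20% by 0.17. A correction for GC content lowered the SD of its pairs only to 0.448 and 0.459 (highest other pair 0.298), which argues against GC content as the whole cause. The gap between long and short transcripts was -0.0674, smaller than the largest gap of the WT libraries, measured the same way (0.149). The mitochondrial transcripts deviated by -3.109, below the lowest 2.5% (-1.09) of nuclear genes of the same GC range, and 0 of 7 marker lists of other cell types were higher there than in both group mates, which argues against added cells of those types in that library. All 7 were lower there than in both group mates, macrophage and monocyte markers at -1.36 against -0.16 and 0.52. Erythroid, platelet, stromal and endothelial cells were not tested. What set this library apart stays open, and beyond added cells of those types no biological explanation was tested.

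The Ifi200 genes changed in both directions. A candidate explanation is that reads only moved between these copies, but the summed FPKM times length over the cluster in BMPR1a-deficient aTreg was 0.585 of that in WT, with no overlap between the groups. A lower interferon response cannot be told apart. The other interferon genes had a median of -0.432, with an SD of 0.438 between single genes. The median of all 12 tested Ifi200 genes, -0.838, lies within that SD of it. That SD describes single genes and not the uncertainty of a median, so this comparison cannot decide the question. The Ifi200 median also mixes genes called lower with Ifi204, which was called higher. Without BMPR1a-deficient replicate 1 the median of the whole interferon list was only -0.19. Ifi213, Ifi206, Ifi208 and Ifi205 then stayed at -3.50, -2.75, -2.53 and -1.45. These genes were named for their large falls, so their values do not decide the question. Variant DNA carried around the cluster cannot be told apart from an effect of the missing receptor, because no sequence was used here: 3 of 128 other tested genes within 10 Mb were called, against 1.30 by chance (one-sided exact hypergeometric test, p = 0.140). An effect of the receptor stays open as a hypothesis.

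The histone list was lower with the preset correlation, although 0 of its 18 genes passed the threshold over all genes and camera gave an adjusted p = 0.785 with an estimated correlation. Fewer cells in S phase may lower histones, but the cell cycle list had a median of 0.305, with 39 of 41 genes positive, and between 0.149 and 0.417 without each library in turn, which argues against this as the whole cause. Its own shift is uncertain, since the call was lost without WT replicate 3, without BMPR1a-deficient replicate 1 and with an estimated correlation (camera, adjusted p = 0.0698, 0.0776 and 0.840), and WT replicate 2 (mean 0.24) lay above BMPR1a-deficient replicates 2 and 3 (0.22 and 0.20). GC content does not account for it, since the histone median after the GC correction was -0.458 and the list stayed past the threshold with the preset correlation. Less capture of RNA without a poly(A) tail cannot be told apart from a change in the cells: 196 other small RNAs had a median of -0.325 (bootstrap 95% interval -0.448 to -0.0241), which includes the histone median of -0.364, and values of such short features are unreliable.

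Within 10 Mb of Bmpr1a, 3 of 72 tested genes were called (Sh3bp5, Wdfy4 and Slmapos2), against 0.761 by chance (one-sided exact hypergeometric test, p = 0.0407, not adjusted for the other windows looked at). The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 split (the real one) gave as many calls as the real 143, and the highest other gave 9. For lists, 3 splits gave at least the real 12, and the highest other gave 15. The splits with 14 and 15 lists were the ones that grouped BMPR1a-deficient replicate 1 with WT replicates 1 and 2 and with WT replicates 2 and 3.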
